A study of Mus musculus with 12 samples.

How the data were processed

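RNA was measured in 12 samples, each the tdTomato-positive (tumor) or tdTomato-negative (microenvironment) cells sorted from the pooled tumors of 3 mice. Per the labels' protocols, total RNA was isolated with Qiagen mini kits, its quality was assessed on an Agilent Bioanalyzer, and 300 ng per sample was reverse-transcribed, amplified and biotinylated by the Eberwine method with an Illumina TotalPrep kit. The arrays were single-colour Illumina mouse bead arrays read, per the submitters' processing notes, with GenomeStudio, whose version was not given in the sources used here. The deposited table gave, for each of 25697 probes and 12 arrays, a linear intensity that had not been normalized, per the file headers, and a detection p-value from the same software, per the file headers. A second deposited table gave processed intensity values of 12824 probes, on a linear scale, with column medians of 94.5 to 104.5. Its lowest value, 21.53, recurred for 1225 to 3928 probes per array, and each column correlated with its own array at 0.979 or above. The normalization and probe selection behind that table stay unknown, so it served only as an alternative.

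The intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc corrected the background by normexp, with the background parameters inferred from the detection p-values, added an offset of 16, and quantile-normalized the 12 arrays together on the log2 scale. Probes with a detection p below 0.01 on at least 2 arrays were kept, which left 11224. Gene names came from the platform annotation: 12096 probes had 1 gene symbol, 0 had several and 13601 had none here. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, in which 12090 of the 12096 matched and 6 did not. The genome build behind the array annotation was not given, and no coordinates are printed. Of the kept probes 10438 had a name. For a gene with several kept probes the brightest by mean over all arrays stood for it, which gave 7894 genes. Quantile normalization forces a common distribution of signal on both fractions, although microenvironment arrays had fewer detected probes, so differences between fractions depend on this choice.

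Samples were grouped by the labels into tumor_F0 and microenvironment_F0 (replicates B2 and B3) and tumor_F4 and microenvironment_F4 (replicates A to D). A linear model with a mean per group was fitted in limma to all 12 arrays, so that the groups shared an estimate of the spread per gene (residual degrees of freedom 8, prior degrees of freedom 3.27), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Every adjusted p of a gene in the text comes from limma. The contrasts were F4 against F0 within each fraction, the difference between these, and tumor against microenvironment fraction within each line. The tumor arrays lay on one chip and the microenvironment arrays on another, so chip and fraction cannot be told apart. On each chip F0 samples took the first positions and F4 samples the others, so position and line cannot be told apart either. A gene whose detection p was 0.01 or more on every array of a group had only a bound there: its fold is given as "at least", the brighter group's mean against the higher, per array, of the lowest signal among detected probes and the gene's own signal.

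Gene lists were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 37 lists of a contrast. The lists, of pathways and of markers of cell types that the fractions could hold, were fixed before the data were examined and held 719 genes, of which 482 list members were measured. Camera with an estimated correlation and fry were run beside it. A list's passing members were also counted with the adjustment over the list alone. The named genes followed a rule set before the data were examined: between F4 and F0, the 10 largest changes each way among passing genes detected throughout the brighter group with all F4 arrays on the same side of both F0 arrays, or, with fewer than 5, the 5 with the smallest p as not passing; between fractions, the 5 largest each way in F4; from each list, members with the smallest p; and always Pgam2, Adh7, Cd274, Pdcd1, Ctla4, Flt3, Mlana, Ptprc, H2-K1 and B2m. Clone-named or predicted genes were skipped when naming. Pgam2 and Adh7 were included from recalled published work on this line.

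The steps were tested on simulated data of 7894 genes with 200 changed, 100 at each fold. For tumor F4 against F0, 9% of the 2-fold and 72% of the 4-fold changes were called, with 4 false calls. For microenvironment F4 against F0 these were 11%, 88% and 4, and for the fractions in F4 35%, 95% and 6. A raised list gave p of 3.02e-33, 2.6e-32 and 8.94e-46 by camera in these comparisons and an unchanged list 0.808, 0.132 and 0.329. These list results followed from the design, since the noise was independent between genes and the raised list held only raised genes. They do not test the list calls for genes that vary together. By the shares of genes called, small changes between F4 and F0 would mostly be missed.

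Replicate names pair the fractions, since per the labels both fractions of a replicate were sorted from the same pool of mice. Deviations from the group means correlated within replicates at 0.393 for B2 and B3, 0.113 for A, 0.107 for B, -0.07 for C and 0.562 for D, while the consensus correlation was 0.198. For A, B and C the microenvironment array of another pool correlated better (0.412, 0.321 and 0.326), while for D none did (at most 0.106). B2 and B3 share a value by construction, as F0 had no other pools. Only D thus correlated best with its own pool, and a best match for a single pool can also arise by chance. The values therefore do not bear out the pairing, which rests on the labels. The F0 and F4 groups share no replicate names, so F4 against F0 has no pairing. Alternatives fixed before the data were examined were no background correction, normexp with an offset of 50, median scaling, the processed table, no filter, a detection p below 0.05, detection on every array of a group, the mean of a gene's probes, trend and robust moderation, array weights, the replicate as a random or fixed block, a 2-fold minimum, the arrays of 1 fraction alone, normalization within a fraction, and each array left out in turn. Added after seeing the data were a marker index as covariate (the mean of the melanocyte list minus that of 6 leukocyte lists, per array), the omission of 3 arrays whose markers lay towards the other fraction, all kept probes including the 786 unnamed, and the fixed block for the gene lists.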

Results

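Gene expression was measured in mouse B16 melanoma tumors on 12 single-colour Illumina bead arrays, which carry 25697 probes. B16 is a pigmented melanoma cell line of C57BL/6 origin. Tumors were grown in C57BL6 mice from F0 cells or from F4 cells, a line that per the labels had acquired resistance to earlier checkpoint inhibitor treatment. Each mouse was given 25000 cells under the skin of the right flank, and tumors were taken at 100 to 400 mm3. For each replicate the tumors of 3 mice were digested, pooled and sorted on the fluorescent protein tdTomato into a positive fraction, called tumor, and a negative fraction, called microenvironment. The F0 tumors gave 2 arrays per fraction (replicates B2 and B3) and the F4 tumors 4 arrays per fraction (replicates A to D), so the replicates were separate pools of mice. The labels differ on treatment. A treatment tag states that the F0 samples had no checkpoint inhibitor before or during the experiment, while the labels describe the F4 tumors as under treatment. The protocol, however, states that both kinds of mice were given the same 3 injections with a vaccine of B16 cells expressing Flt3 ligand. A difference between F4 and F0 is therefore reported as one between the 2 kinds of tumor, which may or may not have differed in current treatment. The series title speaks of patients, but all samples were mouse.

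Between 9302 and 10308 probes were detected on the tumor arrays other than tumor_F4 A, which had 8995, and between 6808 and 9387 on the microenvironment arrays. The mean raw signal was 468.1 to 519.4 on those 5 tumor arrays, 250.5 on tumor_F4 A, and 155.8 to 259.4 on the microenvironment arrays. After normalization 7894 genes were tested. The first principal component held 69.6% of the variance and followed the fraction, with tumor_F4 A at 11.9, microenvironment_F0 B3 at 5.56 and microenvironment_F4 D at 7.45, while the other tumor arrays lay from -71.2 to -42.1 and the other microenvironment arrays from 53.4 to 79.3. Correlations between replicates were 0.960 in the F0 tumor fraction, 0.860 to 0.993 in the F4 tumor fraction, 0.897 in the F0 microenvironment and 0.871 to 0.963 in the F4 microenvironment. No pair of arrays held identical values. The number of arrays limits the precision: the 95% confidence interval of a log2 difference between F4 and F0 extended by a median of 0.76 to either side.

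The first question was how tumor cells of the resistant F4 line differed from F0 cells. The homeobox gene Rhox5, of an X-linked cluster best known from the reproductive tract, was lower in F4 by 45.2-fold, at a log2 signal of 5.35 ± 1.26 (SD, n = 4) against 10.85 ± 0.10 (SD, n = 2), and was detected on 1 of the 4 F4 arrays. This fold compares group means. The F4 mean of Rhox5 was raised by 7.23 on tumor_F4 A, against 4.58 to 4.88 on the other 3 arrays. Lgi4, which encodes a secreted protein of glial cells needed for nerve myelination, was 5.28-fold lower. Fbp2, the muscle isoform of the gluconeogenic enzyme fructose bisphosphatase, was at least 3.02-fold lower, the adenylate cyclase gene Adcy2 at least 2.32-fold lower, and Igfals, which encodes a serum carrier subunit of insulin-like growth factors, at least 1.94-fold lower. Zp3, which encodes a glycoprotein of the egg coat, was at least 1.71-fold higher in F4 and was detected on 4 of 4 F4 arrays and on 0 of 2 F0 arrays. In limma, 1 gene was higher and 6 were lower in F4 at an adjusted p below 0.05, and the adjusted p was 0.0200 for Rhox5, 0.0195 for Lgi4 and Fbp2, 0.0363 for Adcy2, 0.0274 for Igfals and 0.0217 for Zp3. The log2 differences were -5.50 ± 0.71 (SE) for Rhox5, -2.40 ± 0.28 for Lgi4 and 1.62 ± 0.22 for Zp3. The sixth lower gene was the clone-named D630003M21Rik, at least 2.21-fold lower and not detected on any F4 tumor array, which the naming rule skips and which was picked after its value was seen. "At least" marks a gene that was not detected on any array of the dimmer group, so that its fold is a lower bound.

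The 5 genes with the smallest p among those higher in F4 that did not pass were Hs3st1, Pgam2, Slc2a3, Slc12a8 and Ptn. Hs3st1, a heparan sulfate sulfotransferase, stood at 8.80 ± 1.03 in F4 and 5.58 ± 0.09 in F0, a log2 difference of 3.22 ± 0.60 (9.32-fold, adjusted p = 0.121). It passed in 5 of 27 alternatives. These were median scaling (adjusted p = 0.039), array weights (0.000168), without tumor_F4 A (0.0184), the marker index (0.0327) and without 3 arrays (0.0194), the last pair chosen after seeing the data. Pgam2, the muscle isoform of the glycolytic enzyme phosphoglycerate mutase, stood at 8.83 ± 0.29 and 5.21 ± 0.42, a difference of 3.62 ± 0.74 (12.3-fold, adjusted p = 0.191), and was detected on 1 of the 2 F0 arrays. Pgam2 passed in 4 of 27 alternatives: median scaling (adjusted p = 0.0285), array weights (0.000523), the arrays of the fraction alone (0.0433) and without microenvironment_F4 D (0.0314). The glucose transporter Slc2a3 differed by 1.64 ± 0.31 (3.12-fold, adjusted p = 0.121), Slc12a8 by 1.37 (at least 1.79-fold, adjusted p = 0.118) and the growth factor gene Ptn by 1.03 (at least 1.18-fold, adjusted p = 0.191, detected on 2 of 4 F4 arrays). Every F4 array lay above both F0 arrays for each of these 5 genes. Of the genes named in advance, Adh7, an alcohol dehydrogenase that oxidizes retinol, differed by 1.29 ± 0.55, the melanocyte antigen gene Mlana by -0.12 ± 0.65, the PD-L1 gene Cd274 by 0.19 ± 0.54, the class I genes H2-K1 by 0.57 ± 0.69 and B2m by 0.29 ± 0.23, and Ctla4, detected on 1 of 4 and 0 of 2 arrays, by 0.61 (0.0207 without tumor_F4 A), all at an adjusted p of 1.0.

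**Figure D1:**
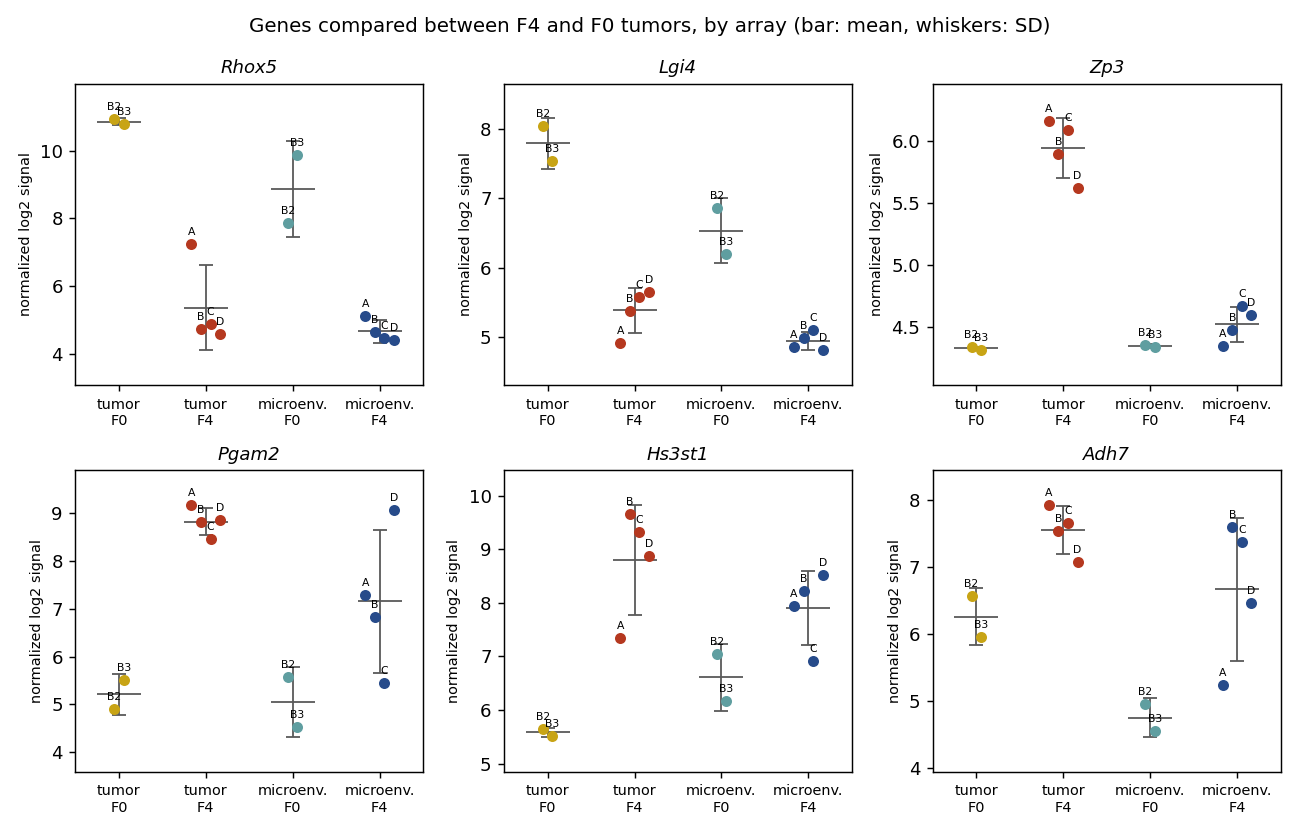
Normalized log2 signal of 6 genes on each of the 12 arrays, grouped by fraction and line, with replicate names beside the points, bars at the group means and whiskers of 1 SD. Rhox5 lay at 10.92 and 10.78 on the F0 tumor arrays and at 7.23 on tumor_F4 A, and at 4.58 to 4.88 on the other 3 F4 tumor arrays.

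These counts rested on few arrays and on a spread shared with the microenvironment arrays. With the arrays of the tumor fraction alone, limma called none of these 7 genes and only Pgam2. The adjusted p was then 0.15 for Rhox5 and 0.148 for Lgi4 and Zp3. With normalization within the fraction no gene was called. No gene passed when tumor_F0 B2, tumor_F0 B3, tumor_F4 B, tumor_F4 C or microenvironment_F4 B was left out, which gave 0 higher and 0 lower in each case. The differences themselves kept their direction, and over the omission of each of the 12 arrays ran from -6.12 to -5.24 for Rhox5, -2.65 to -2.15 for Lgi4 and 1.54 to 1.73 for Zp3. Without tumor_F4 A, 2 genes were higher, Hs3st1 among them, and 3 were lower. The Rhox5 difference was then -6.12, with Rhox5 not detected on the remaining F4 tumor arrays, so its size is uncertain. Without tumor_F4 D the counts were 1 and 2, and without microenvironment_F4 D they were 2 and 4. Without microenvironment_F0 B2 or B3 they were 2 and 8. With median scaling in place of quantile normalization, 11 genes were higher and 2 lower, a share of 84.6% higher against 14.3%. Over all genes, 165 (2.09%) had an unadjusted p below 0.05, and for 1084 genes (13.7%) the F4 and F0 arrays did not overlap, where chance gives 13.3% for 2 arrays against 4.

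Among 37 gene lists fixed in advance, camera called 16 higher and 1 lower in F4 tumor cells, with no member of any list passing the test over all genes. No list call held with an estimated correlation (smallest adjusted p = 0.725 with an estimated correlation), and fry called 0 lists. Several leukocyte lists were among those called. The T cell list had a median log2 difference of 0.99 with 11 of 12 genes above 0 (adjusted p = 0.00268), the neutrophil list 0.90 with 11 of 11 above 0 (adjusted p = 0.000479), the macrophage list 0.81 (adjusted p = 0.00268), the cytotoxic lymphocyte list 0.97 (adjusted p = 0.0104) and the inflammatory cytokine list 0.87 (adjusted p = 0.00268). S100a8, a neutrophil calcium-binding protein gene, differed by 2.19 ± 0.83, and by 1.40 without tumor_F4 A. The skeletal muscle list had a median of 0.83 (adjusted p = 0.000668), with Des at 1.22 ± 0.42, and immediate early and heat shock genes one of 0.48 (adjusted p = 0.000479). Smaller medians were found for class I presentation (0.35, adjusted p = 0.00115), the type I interferon response (0.28, adjusted p = 0.000762, Ifi35 at 0.82 ± 0.33), class II presentation (0.48, adjusted p = 0.00525), immune checkpoints (0.50, adjusted p = 0.00637, Lgals9 at 0.80 ± 0.32) and alternatively activated macrophages (0.51, adjusted p = 0.00881). Endothelial (0.72), keratinocyte (0.55), citrate cycle (0.09) and NRF2 target (0.11) genes had adjusted p of 0.0396, 0.0160, 0.0430 and 0.0396. Regulatory T cells (0.47, adjusted p = 0.0825), NK cells (0.22, adjusted p = 0.269), dendritic cells (0.14, adjusted p = 0.329), B cells (0.15, adjusted p = 0.673) and mast cells (-0.23, adjusted p = 0.346) were not called. Fatty acid and cholesterol synthesis was the list called lower, with a median of -0.30, 14 of 15 genes below 0 (adjusted p = 0.0173) and Srebf2, a transcription factor of this pathway, at -0.52 ± 0.28. Adjusted over the list alone, 1 gene of the muscle list passed (Pgam2) and 2 of the glycolysis list (Slc2a3 and Pgam2).

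The array tumor_F4 A carried much of these shifts: its T cell list mean was 8.19 against 4.56 to 5.58 on the other 3 F4 tumor arrays, its muscle list mean 8.23 against 5.71 to 5.80, its macrophage list mean 9.88 and its melanocyte list mean 9.64 against 10.36 to 10.55. Without it, 2 lists were called, the type I interferon response (0.12) and immediate early genes (0.35), both at an adjusted p of 0.0495. Without tumor_F0 B3, 7 lists were called, and the interferon gamma response was then lower by a median of -0.62 (adjusted p = 3.13e-05).

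**Figure D2:**
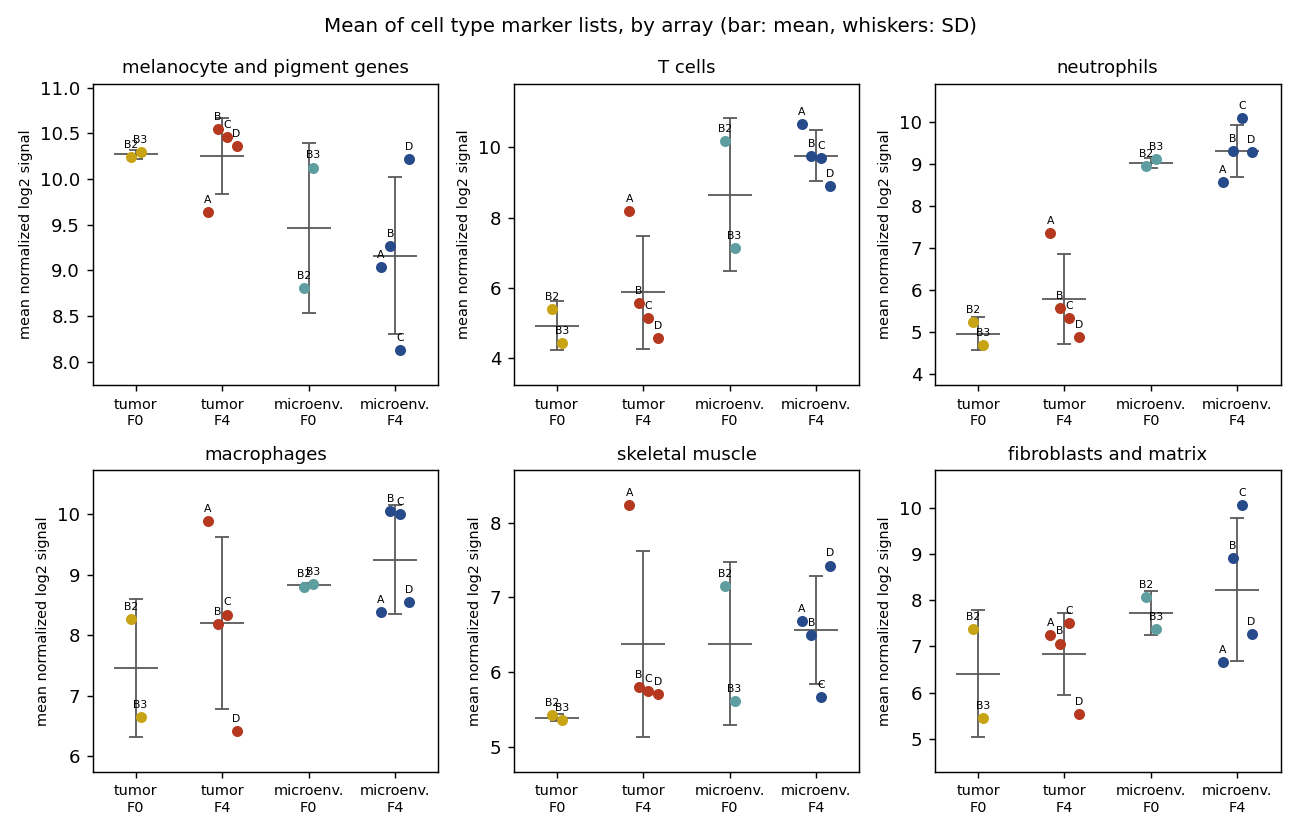
Mean normalized log2 signal of 6 marker lists on each of the 12 arrays, grouped by fraction and line, with replicate names beside the points, bars at the group means and whiskers of 1 SD. The skeletal muscle list lay at 8.23 on tumor_F4 A and at 5.71 to 5.80 on the other F4 tumor arrays.

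The second question was how the cells around the tumor differed. In the F4 microenvironment the signal of Arhgap29 was 7.07 ± 0.34 (SD, n = 4) against 4.97 ± 0.50 (SD, n = 2), at least 1.94-fold higher, with an adjusted p of 0.311. Rhox5 and Lgi4, both lower in the F4 tumor fraction, were at least 7.98-fold and 1.57-fold lower in the F4 microenvironment, with adjusted p of 0.343 and 0.346. The log2 differences were 2.09 ± 0.32 (SE), -4.22 ± 0.71 and -1.59 ± 0.28. Adh7 and Pgam2 were not detected in the F0 microenvironment and differed by 1.91 ± 0.55 (at least 1.47-fold) and 2.10 ± 0.74 (at least 2.06-fold), both at an adjusted p of 0.999. No gene passed the limma test, with 193 genes (2.44%) at an unadjusted p below 0.05. The Rhox5 difference ran from -5.22 to -3.22 when single arrays were left out. Without tumor_F4 A, an array outside this comparison that enters the estimate of the spread, Rhox5 was the 1 gene that passed (adjusted p = 0.0200). No other alternative called a gene, setting aside the omission of the 3 arrays whose markers lay towards the other fraction (tumor_F4 A, microenvironment_F0 B3 and microenvironment_F4 D). That choice was made after seeing the data and left only microenvironment_F0 B2 in its group, so its calls are not given.

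Of the other genes with the smallest p in this fraction, all at an adjusted p of 0.999, Fyco1, Vrk2, Slc12a8 and Zdhhc3 were each detected on 2 of 4 F4 arrays and on 0 of 2 F0 arrays, and no size is given for them, since the lower bound of the fold was under 1. The other probe of Zdhhc3, detected on 2 of the 12 arrays, differed from it with -0.20. The cadherin gene Cdhr2 differed by -1.04, at least 1.20-fold, Plekhj1, detected on 1 of 4 and 1 of 2 arrays, by -1.26, and Calr3, detected on 1 of 4 and 2 of 2, by -1.68. The other 2 probes of Calr3 were detected on 1 and 0 of the 12 arrays and were left out. The differences were 0.09 for Cd274, 0.56 ± 0.88 for Ctla4, -0.40 ± 0.65 for Mlana, 0.80 ± 0.69 for H2-K1 and 0.23 for B2m, at the same adjusted p.

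Camera called 8 lists higher and 6 lower in the F4 microenvironment, and again no member passed over all genes. No call held with an estimated correlation (smallest adjusted p = 0.918 with an estimated correlation), and fry called 0 lists. The T cell list had a median difference of 1.23 with 12 of 12 genes above 0 (adjusted p = 0.00162, Cd28 at 1.49 ± 0.80, or 2.99 and -0.0133 without microenvironment_F0 B2 and B3), and the cytotoxic lymphocyte list one of 1.08 (adjusted p = 0.0133). The NK cell list was lower, at a median of -0.47 (adjusted p = 0.0376), with the receptor genes Klra7 at -2.55 ± 0.81 (-0.68 without microenvironment_F0 B2 and -4.42 without B3) and Klra4 at -1.94 ± 0.91 (-0.0865 and -3.78). Class I presentation (0.50) and the type I interferon response (0.35) each had an adjusted p of 0.00488, alternatively activated macrophages (0.65) and immediate early genes (0.44) one of 0.0376, and inflammatory cytokines (0.51) and fibroblasts (0.40) one of 0.0394. Lower were oxidative phosphorylation, at -0.22 with 41 of 44 genes below 0 (adjusted p = 0.00488), cell cycle genes, at -0.33 with 18 of 22 below 0 (adjusted p = 0.00776, Tk1 at -1.04 ± 0.61), fatty acid and cholesterol synthesis, at -0.20 with 15 of 15 below 0 (adjusted p = 0.0394, Scd1 at -0.78 ± 0.47), the hypoxia response, at -0.24 (adjusted p = 0.0356, Vegfa at -0.61 ± 0.23), and ribosomal proteins, at -0.10 (adjusted p = 0.0376). The melanocyte list, not called here, also had a negative median, -0.43 with 12 of 14 genes below 0 (adjusted p = 0.220). With the marker index of the arrays as a covariate, chosen after seeing the data, 3 lists were called: T cells, NK cells and class I presentation. That index is built from the melanocyte list and 6 leukocyte lists, T cells and NK cells among them, so which lists stay called under it is partly set by construction. Adjusted over the list alone, 1 gene of the alcohol and aldehyde list passed (Adh7). The arrays microenvironment_F0 B2 and B3 differed widely, with T cell list means of 10.18 and 7.12 and NK cell list means of 9.89 and 6.64. Without B3, 4 lists were called, among them NK cells at -3.05 and alternatively activated macrophages at 1.29, and the T cell list was not. Without microenvironment_F4 C 2 lists were called, and without microenvironment_F4 B 8.

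Whether the difference between F4 and F0 itself differed between the fractions was tested as an interaction. No gene passed in limma, with 97 genes (1.23%) at an unadjusted p below 0.05, and none passed under any alternative. The interaction was 1.51 ± 1.04 for Pgam2, -0.62 for Adh7, 0.09 for Cd274, 0.05 for Ctla4, 0.28 for Mlana, -0.23 for H2-K1 and 0.06 for B2m, all at an adjusted p of 1.0, so neither the Rhox5 nor the Pgam2 difference was shown to be limited to a fraction. Camera called 4 lists whose change was more positive in the tumor fraction: oxidative phosphorylation, at 0.26 with 43 of 44 genes above 0 (adjusted p = 0.000356), NK cells, at 1.15 with 7 of 7 (adjusted p = 0.0177), skeletal muscle, at 0.73 with 11 of 11 (adjusted p = 0.0177), and cell cycle genes, at 0.42 with 19 of 22 (adjusted p = 0.0205). No member passed, over all genes or adjusted over the list alone, and no call held with an estimated correlation (adjusted p = 0.996 with an estimated correlation). With the replicate as a fixed block 5 lists were called. Leaving out an array also changed the direction of calls. Without tumor_F0 B3, 6 lists were more positive and 6 more negative in the tumor fraction, and without microenvironment_F0 B2, 7 and 3. Without tumor_F0 B2 all 12 and without microenvironment_F0 B3 all 8 were more positive. In either direction the count was 10 without tumor_F4 D, 7 without microenvironment_F4 D and 1 without microenvironment_F4 C. Without tumor_F4 A it was again 4, with the muscle and NK cell lists replaced by T cells and cytotoxic lymphocytes, at -1.03 and -0.84.

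The sort itself was examined by comparing the fractions of the F4 tumors. The microenvironment fraction held far more transcript of neutrophil and lymphocyte genes: the calprotectin genes S100a9 and S100a8 were 37.2-fold and 36.4-fold higher there, the T cell adapter gene Sh2d2a 36.5-fold, the histidine decarboxylase gene Hdc 33.4-fold and the cytotoxic granule gene Nkg7 32.9-fold. The tumor fraction was higher in the methyltransferase gene Eef1akmt1 (8.39-fold), the calpain gene Capn6 (6.66-fold), Sh3tc2 (5.84-fold), Cmtm5 (5.57-fold) and the desmosomal gene Pkp2 (5.27-fold), and in Mlana (3.07-fold). Ctla4 was 14.7-fold, H2-K1 4.0-fold and Cd274 2.80-fold higher in the microenvironment. In limma 1053 genes were higher in the tumor fraction and 886 in the microenvironment, with adjusted p of 0.00406 for S100a9, S100a8 and Hdc, 0.0198 for Sh2d2a, 0.0248 for Nkg7, 0.0133 for Eef1akmt1 and Ctla4, 0.0179 for Capn6, 0.0111 for Sh3tc2, 0.0249 for Cmtm5, 0.0247 for Pkp2, 0.0468 for Mlana, 0.0321 for H2-K1 and 0.0364 for Cd274. The log2 differences were -5.22 ± 0.68 (SE, n = 4 pools) for S100a9, 3.07 ± 0.57 for Eef1akmt1 and 1.62 ± 0.53 for Mlana. Single arrays moved several of these by over 1.5 times. Without tumor_F4 A the differences were -6.05 for S100a9, -5.98 for S100a8, -6.28 for Sh2d2a, -5.77 for Hdc, -6.32 for Nkg7 and -4.47 for Ctla4. Without tumor_F4 D, Sh2d2a (-4.45, adjusted p = 0.0665) and Nkg7 (-4.29, adjusted p = 0.0787) no longer passed. Without microenvironment_F4 D, Cmtm5 differed by 3.10 and Pgam2 by 2.31 (adjusted p = 0.00581). In the microenvironment, Eef1akmt1 was detected on 1 of 4 arrays, Capn6, Cmtm5 and Pkp2 on 2 and Sh3tc2 on 3, and in the tumor fraction Ctla4 was detected on 1 of 4 arrays and S100a9, Sh2d2a, Hdc, Nkg7 and H2-K1 on 3. B2m (-0.30, adjusted p = 0.218), Pgam2 (1.68, adjusted p = 0.0591, and 0.0384 with the pool of mice as a fixed block) and Adh7 (0.88, adjusted p = 0.142) did not pass. Pdcd1, Flt3 and Ptprc had no named probe here.

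Camera called 6 lymphocyte and neutrophil lists higher in the microenvironment fraction. With an estimated correlation the adjusted p was 0.160 for B cells and 0.484 for the other 5 lists. All 12 measured T cell genes passed (median log2 difference -4.07), among them Cd2 (23.7-fold, adjusted p = 0.0161) and Cd28 (11-fold, adjusted p = 0.0140), and 12 passed adjusted over the list alone. Of the cytotoxic lymphocyte genes 9 of 10 passed (median -4.23, 10 adjusted over the list alone), with the perforin gene Prf1 20.9-fold and the chemokine gene Ccl5 18.6-fold higher. Of the neutrophil genes 11 of 11 passed (median -3.5, 11 adjusted over the list alone), with Retnlg at least 12.1-fold higher. Of the NK cell genes 3 of 7 passed (median -2.21, 5 adjusted over the list alone), with Klrd1 17.2-fold and Klrk1 at least 2.84-fold higher. Regulatory T cell genes passed in 5 of 6 cases (median -3.11, 5 adjusted over the list alone), with Tnfrsf4 13.7-fold and the lineage factor gene Foxp3 5.41-fold higher. All 4 B cell genes passed (median -1.95, 4 adjusted over the list alone), with Fcrla at least 3.5-fold higher. Camera gave adjusted p of 1.25e-08, 3.36e-06, 5.41e-10, 0.000312, 3.42e-05 and 0.000228 for T cells, cytotoxic lymphocytes, neutrophils, NK cells, regulatory T cells and B cells. Without tumor_F4 A the differences were -5.51 for Cd2, -5.56 for Prf1, -5.32 for Ccl5 and -5.01 for Klrd1, against -4.56, -4.38, -4.21 and -4.11 with it. Without tumor_F4 D, Ccl5 was at -3.60 and did not pass (adjusted p = 0.0688). In the tumor fraction Klrd1 and Foxp3 were detected on 1 of 4 arrays, Cd2 and Cd28 on 2 and Tnfrsf4 on 3, so that these folds were taken partly against arrays where the gene was not detected.

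Camera also called 9 myeloid, antigen presentation, checkpoint, interferon and stress lists higher in the microenvironment. With an estimated correlation the adjusted p was 0.544 for macrophages and 0.484 for the other 8. Of the inflammatory cytokine genes 9 of 13 passed (median -2.52, 10 adjusted over the list alone, adjusted p = 7.13e-06), with Cxcl2, a neutrophil chemokine, 9.76-fold and Nfkbia 6.83-fold higher in the microenvironment. Class II presentation had 4 of 11 (median -2.16, 5 adjusted over the list alone, adjusted p = 4.01e-05, H2-Oa 4.92-fold) and dendritic cells 3 of 9 (median -1.56, 5 adjusted over the list alone, adjusted p = 0.00390, Itgae 6.80-fold). The macrophage list had 1 of 13, Cd14 at 7.57-fold (median -0.83, 0 adjusted over the list alone, adjusted p = 0.0243), and alternatively activated macrophages 1 of 9, Chil3 at 6.95-fold (median -0.71, 1 adjusted over the list alone), at an adjusted p of 0.0666. Immune checkpoints had 9 of 14 (median -2.23, 1 higher and 12 lower adjusted over the list alone, adjusted p = 3.36e-06), with the costimulatory receptor gene Icos 10.9-fold higher. Class I presentation had 4 of 17 (median -1.06, 4 adjusted over the list alone, adjusted p = 0.00130, Tapbp 3.21-fold). The interferon gamma response had 4 of 17, including both receptor genes Ifngr2 (8.67-fold) and Ifngr1 (8.06-fold) and the kinase gene Jak2 (3.42-fold), with 1 gene higher in the tumor fraction (median -1.03, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00200). The type I interferon response had 1 of 16, Rsad2, with an adjusted p of 0.0455 and of 0.0535 with the fixed block (median -0.47, 0 adjusted over the list alone, adjusted p = 0.00277), and immediate early and heat shock genes 5 of 16 (median -1.05, 6 adjusted over the list alone, adjusted p = 0.00274), with Hspa1a 6.03-fold, Egr1 4.27-fold and Junb 3.45-fold. Without tumor_F4 A the differences were -3.73 for Cd14, -3.99 for Cxcl2, -3.46 for Chil3, -3.89 for Ifngr2 and -3.31 for Hspa1a, against -2.92, -3.29, -2.80, -3.12 and -2.59 with it. Without tumor_F4 D, Cd14 was at -2.11 and did not pass (adjusted p = 0.107). In the tumor fraction H2-Oa and Chil3 were detected on 1 of 4 arrays, Icos on 2 and Itgae on 3.

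Among other cell types, the erythroid, fibroblast and mesenchymal lists were called higher in the microenvironment (adjusted p = 0.484 with an estimated correlation for each). Of the erythroid genes 2 of 3 passed (median -3.5, 3 adjusted over the list alone, adjusted p = 0.00468): the heme synthesis gene Alas2 was 24.5-fold and the anion exchanger gene Slc4a1, detected on 1 of 4 tumor arrays, 11.3-fold higher. Alas2 differed by -5.44 without tumor_F4 A, against -4.62 with it. The fibroblast list had a median of -1.31 (adjusted p = 0.00228) with 1 of 14 passing, Col1a2, and 0 adjusted over the list alone, while the proteoglycan gene Dcn had an adjusted p of 0.0791, and of 0.0321 with the pool of mice as a fixed block (log2 difference -2.79, and -1.81 without tumor_F4 D). Mesenchymal and invasion genes had a median of -0.99 (adjusted p = 0.0162) with 2 of 13 passing, Zeb1 and Cdh1, and 2 adjusted over the list alone. Cdh1 encodes the epithelial cadherin, so the genes that passed do not show a mesenchymal shift. Melanocyte genes were higher in the tumor fraction at a median of 1.28 (adjusted p = 0.0210, and adjusted p = 0.529 with an estimated correlation), with 2 of 14 passing, Mlana and Cited1 (3.66-fold), and 0 adjusted over the list alone. Cited1 was detected on 2 of 4 microenvironment arrays and differed by 2.51 without microenvironment_F4 D, against 1.87 with it. Endothelial cells (median -0.96, adjusted p = 0.0735, Eng 2.02-fold higher in the tumor fraction), adipocytes (-1.13, adjusted p = 0.0756, Lep lower in the tumor fraction), keratinocytes (-0.69, adjusted p = 0.187, Ly6d lower and Lgals7 higher), mast cells (-0.75, adjusted p = 0.311) and skeletal muscle (-0.31, adjusted p = 0.917, Ckm at least 1.08-fold higher) were not called. On the microenvironment arrays the melanocyte list mean reached 10.12 on microenvironment_F0 B3 and 10.22 on microenvironment_F4 D, against 8.13 to 9.27 on the other 4, so these arrays lay nearer to the tumor fraction.

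Camera called 5 lists of energy, lipid synthesis and cell cycle genes higher in the tumor fraction, with 2 to 16 members passing (adjusted p = 0.484 with an estimated correlation for each). Of 44 measured oxidative phosphorylation genes, 44 were above 0 and 16 passed (median 0.66, 25 adjusted over the list alone, adjusted p = 3.79e-06), with Ndufb8 of complex I 1.87-fold higher. The citrate cycle had 6 of 18 (median 0.81, 7 adjusted over the list alone, adjusted p = 0.00228), with Suclg2 3.13-fold and Mdh2 2.01-fold higher. Glycolysis had 7 of 18 higher and 1 lower (median 0.74, 9 higher and 1 lower adjusted over the list alone, adjusted p = 0.00699), with Aldoc 3.06-fold and the pyruvate kinase gene Pkm 1.76-fold higher. Cell cycle genes had 4 of 22 (median 0.99, 3 adjusted over the list alone, adjusted p = 0.00182), with the replication helicase genes Mcm2 3.00-fold and Mcm6 2.29-fold higher. Fatty acid and cholesterol synthesis had 2 of 15 (median 1.07, 2 adjusted over the list alone, adjusted p = 0.00594), with Lss 2.48-fold and Dhcr7 at least 1.34-fold higher. NRF2 targets (median 0.44, adjusted p = 0.274, Gpx4 2.05-fold), alcohol and aldehyde metabolism (0.56, adjusted p = 0.198, Akr1b8 4.28-fold), fatty acid oxidation (0.43, adjusted p = 0.120, Acadl 2.95-fold), the hypoxia response (0.39, adjusted p = 0.475, Egln3 2.94-fold lower), Wnt genes (0.83, adjusted p = 0.465), the unfolded protein response (0.19, adjusted p = 0.790) and ribosomal proteins (0.12, adjusted p = 0.725) were not called. In these 7 lists, in that order, 5 of 17, 2 of 9, 2 of 14, 5 of 18, 1 of 5, 2 of 15 and 1 of 27 genes were higher, and 7, 1, 2, 5, 1, 0 and 0 adjusted over the list alone, while 1 hypoxia gene and 1 ribosomal protein gene were lower by either count.

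**Figure D3:**
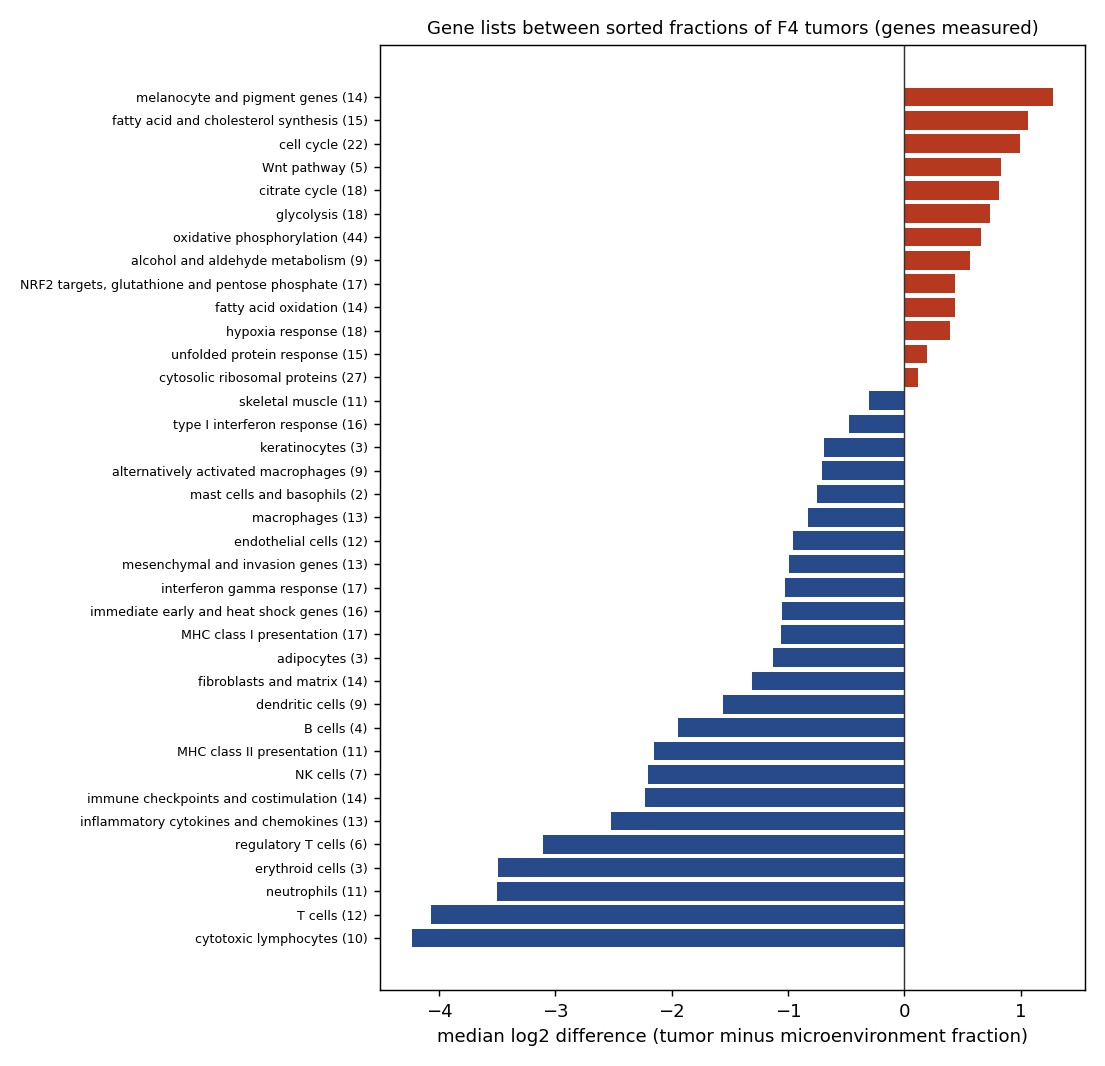
Median log2 difference between the tumor and microenvironment fractions of F4 tumors for each of the 37 gene lists, with the number of measured genes in brackets; bars to the right are higher in the tumor fraction. The medians ran from -4.23 for cytotoxic lymphocytes to 1.28 for melanocyte and pigment genes.

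The fractions lay on separate chips, so fraction and chip cannot be told apart. Median scaling moved the median log2 difference of all genes from 0.20 to -0.32 and the split to 414 higher and 2201 lower (15.8% higher against 54.3%). Camera then called 7 lists higher and 11 lower, against 6 and 18, though no called list turned the other way. With the pool of mice as a fixed block, 1483 genes were higher and 1133 lower, and as a random block 1834 and 1226. The counts were 33 and 53 without tumor_F4 B, 34 and 51 without tumor_F4 C, 31 and 60 without tumor_F4 D, 88 and 145 without microenvironment_F4 C, 211 and 341 without microenvironment_F4 B, 411 and 408 without microenvironment_F4 A, and 604 and 694 without tumor_F0 B2 or B3. They were 1773 and 1209 without tumor_F4 A and 1960 and 1310 without microenvironment_F4 D. Of the 63 named genes past the threshold, 11 remained past it without tumor_F4 B, 12 without tumor_F4 C, 11 without tumor_F4 D, 21 without microenvironment_F4 C, 33 without microenvironment_F4 B and 36 without microenvironment_F4 A, and none changed direction. Without the 3 arrays whose markers lay towards the other fraction, 2768 genes were higher and 1712 lower. Since these arrays were picked for that trait, a wider difference follows from the choice.

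In the F0 tumors, with 2 pools, neutrophil genes again led the difference between fractions: S100a8 was 141.2-fold higher in the microenvironment (log2 difference -7.14 ± 0.96, adjusted p = 0.00866, detected on 1 of 2 tumor arrays) and Retnlg at least 16-fold (adjusted p = 0.00346). The costimulatory receptor gene Tnfrsf4, detected on 1 of 2 tumor arrays, was 23-fold higher there (adjusted p = 0.0303). Its difference of -4.52 was -3.62 without microenvironment_F0 B2 (adjusted p = 0.236) and -5.43 without B3. Also higher there were the B cell genes Fcmr, at least 12.1-fold (adjusted p = 0.0219), and Fcrla, at least 3.36-fold (adjusted p = 0.00676). In limma 21 genes were higher in the tumor fraction and 51 lower. Camera called 2 lists higher, fatty acid and cholesterol synthesis (median 0.93, adjusted p = 0.0116) and oxidative phosphorylation (0.41, adjusted p = 0.0234), and 21 lower, led by neutrophils (-3.90, adjusted p = 7.45e-12, 4 of 11 passing and 11 adjusted over the list alone) and T cells (-4.48, adjusted p = 1.43e-07, 1 of 12 passing and 10 adjusted over the list alone). None held with an estimated correlation (smallest adjusted p = 0.0587 with an estimated correlation, for B cells), and fry called 7 lists. The log2 differences were 1.34 for Mlana (adjusted p = 0.280), -1.58 for Cd274 (0.157), -1.77 for H2-K1 (0.20), -0.37 for B2m (0.382) and 0.16 for Pgam2 (0.914), while Ctla4 was at least 11.1-fold higher in the microenvironment (0.0736) and Adh7 at least 1.11-fold higher in the tumor fraction (0.178). With the pool as a fixed block the adjusted p was 0.0288 for Ctla4 and 0.0436 for H2-K1, and 130 genes were higher and 373 lower, and as a random block 230 and 356. Both genes depended on single arrays: Ctla4 differed by -2.26 without microenvironment_F0 B2 and by -5.59 without B3 (adjusted p = 0.0196). H2-K1, detected on 1 of 2 arrays of either fraction, differed by -0.53 and -3.0 (adjusted p = 0.0464). Cd274 ran from -2.29 to -0.86 and Mlana from 0.52 to 2.16. Median scaling gave 16 higher and 1028 lower, a median difference of -0.35 against 0.19. Leaving out tumor_F0 B2 or B3 left 0 higher and 1 or 2 lower, and leaving out microenvironment_F0 B2 left 0 and 9. Leaving out microenvironment_F0 B3 gave 277 and 306, tumor_F4 A 208 and 393, microenvironment_F4 D 65 and 137, tumor_F4 B 4 and 24, tumor_F4 C 5 and 27, tumor_F4 D 5 and 36, and microenvironment_F4 B 5 and 33. Without tumor_F0 B3, 14 lists were called.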

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

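The tests of explanations in this part were chosen only after the results they bear on had been seen, while the tests of differences between fractions were planned.

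The array tumor_F4 A stood apart from the other 3 F4 tumor arrays. Its NK cell list mean was 6.25 (others 4.41 to 4.66), its skeletal muscle list mean 8.23 (others 5.71 to 5.80), its log2 signal of Ctla4 7.09 (others 4.55 to 4.90), of Rhox5 7.23 (others 4.58 to 4.88) and of Sh3tc2 7.69 (others 9.12 to 9.29), and its mean raw signal 250.5 (others 488 to 519). Elsewhere tumor_F4 C was low in Cmtm5, at 7.77 (others 8.16 to 8.24), and microenvironment_F4 D in Ctla4, at 8.29 (others 9.48 to 9.56). These 8 values came from 146 tests of groups of 4 arrays by Dixon's ratio, of which chance picks out about 5%, so their number is near that of chance. Of the 8, 6 were on tumor_F4 A, and values of the same array are not independent.

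For that array, all 6 lymphocyte and neutrophil lists lay above every other tumor array and below the microenvironment array of the same pool, so RNA of tdTomato-negative cells of the pool may account for them. For the low signal of the array, the mean excess of 2.40 over 50 genes had a percentile of 100 among 10000 random sets (highest 0.688). These sets were matched on the mean level over all 12 arrays, which the microenvironment arrays raise for such lists. On tumor_F4 B, C and D the lists lay low (T cells 4.56 to 5.58, NK cells 4.41 to 4.66), so the sets cannot decide this explanation. An exchanged label is argued against, since the marker index of microenvironment_F4 A was 0.0124 against 4.52 on the lowest other tumor array. The macrophage list lay 1.5 ± 0.249 (SE over genes) above microenvironment_F4 A with 13 of 13 genes higher, and the muscle list 1.52 ± 0.135 above it with 10 of 10 genes higher. This argues only against admixture of tdTomato-negative cells in the proportions of that array. It compares single arrays on separate chips, and an SE over genes that vary together does not measure the spread between arrays. Admixture in other proportions is not excluded. For Rhox5 such admixture is argued against, since its highest F4 microenvironment value was 5.12, against 7.23 on tumor_F4 A. RNA of F0 tumor cells as a source of Rhox5, at a share of 6.8%, cannot be told apart from other sources: 1 of 4 other genes higher in F0 lay above tumor_F4 B, C and D (Fbp2, at 5.28), Lgi4 did not (4.92 against 5.87 predicted), and most of these genes were not detected on the F4 arrays. A real difference of that pool in macrophage content, adjacent muscle or Rhox5 stays open and was not tested, as the labels give no group for it.

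Pgam2 was 12.3-fold higher in F4 than in F0 tumor cells without passing the test (adjusted p = 0.191), though it passed in 4 of 27 alternatives. RNA of muscle tissue as a whole is argued against: on tumor_F4 B, C and D the other 10 muscle genes rose over F0 by a median log2 of 0.0931 (SE 0.129, highest 0.924 for Des), against 3.5 for Pgam2. A difference between the F4 and F0 lines, or in their treatment, may account for it and stays among the open explanations as untested. Array position follows the line on both chips, and a single probe measured the gene.

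In the microenvironment fraction, Rhox5 and Pgam2 differed between F4 and F0 in the direction of the tumor fraction, and so did Adh7 and Arhgap29. RNA of tumor cells in the negative fraction may account for Rhox5 and Pgam2, but the test cannot decide it. The share of tumor RNA that their levels would need passed that of every pigment gene in 0 of 6 combinations of gene and array. On microenvironment_F0 B3 and microenvironment_F4 D the highest pigment gene stood at 127% and 132%. Admixture cannot exceed the tumor level itself, so it could not pass there. The measure is also inexact, with Pgam2 at 118% on microenvironment_F4 D. Rhox5 stood at 50.3% on microenvironment_F0 B3, below every pigment gene there (lowest 69.5%). On the other arrays the gene tested lay within the range of the pigment genes. Tumor-cell RNA is argued against for Adh7 and Arhgap29, whose shares passed every pigment gene in 5 of 8 combinations (2 for Adh7 and 3 for Arhgap29). On microenvironment_F4 C, for example, they were 84.3% and 138% against 5.80% to 31.0%. Expression of these genes in tdTomato-negative cells stays open and was not tested.

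In the test of the difference itself, camera called 4 lists whose change from F0 to F4 differed between the fractions. These were NK cells (1.15), skeletal muscle (0.726), oxidative phosphorylation (0.258) and cell cycle genes (0.421), with none called under an estimated correlation or by fry. Without tumor_F4 A, NK cells and skeletal muscle were no longer called. T cells (-1.03) and cytotoxic lymphocytes (-0.842) were then called, in the other direction. A probe with no gene name here, which the comparisons did not use, was lower in F4 than in F0 tumor cells by a log2 difference of -1.72 (SE 0.202, adjusted p = 0.0161 in limma over all probes), at 6.27 on both F0 arrays and 4.47 to 4.64 on the F4 arrays. Fbp2, not detected on any F4 tumor array, lay at 4.43 to 5.28 there, so the size of this difference is uncertain.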

How the results depend on the processing

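Each array left out in turn and the settings listed under processing were planned, while the marker index, the omission of 3 arrays, all kept probes and the fixed block for gene lists were chosen only after the results were seen. Of 131 gene values, 107 kept their sign in all alternatives run. The cause of the changes below was not tested, except that fewer arrays leave fewer degrees of freedom. Signal over background limited the microenvironment arrays, at 2.32 to 3.93 against 8.35 to 9.90 on the tumor arrays other than tumor_F4 A (3.86). Among the lists, the fixed block added B cells to the calls for the difference of changes, and for the fractions in F0 it added the citrate cycle and lost keratinocytes and adipocytes.

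For tumor F4 against F0 (1 higher, 6 lower), the counts were 0 and 2 without background correction, 0 and 3 with normexp, 11 and 2 with median scaling, 0 and 5 with the processed table, 2 and 13 with trend and robust moderation, 51 and 49 with array weights, 1 and 5 with a random replicate block, 1 and 0 with the arrays of the fraction alone, 0 and 0 with normalization within the fraction, 4 and 11 with the marker index and 6 and 8 without the 3 arrays. For the microenvironment (0 and 0), the last left only microenvironment_F0 B2 in its group, so no count is given for it. For the fractions in F4 (1053 and 886), they were 414 and 2201 with median scaling, 3671 and 2228 with array weights, 1834 and 1226 with a random replicate block, 1483 and 1133 with a fixed one, 603 and 734 at a 2-fold minimum, 0 and 1 with the marker index and 2768 and 1712 without the 3 arrays. For the fractions in F0 (21 and 51), they were 0 and 15 without background correction, 1 and 18 with normexp, 16 and 1028 with median scaling, 41 and 171 with array weights, 230 and 356 with the random and 130 and 373 with the fixed block, 0 and 1 with the marker index, 1537 and 1084 without the 3 arrays and 33 and 70 over all probes. The marker index separates the fractions by construction, which removes most of their difference. Omitting the 3 arrays, picked for lying towards the other fraction, widens that difference by construction. For the fractions in F0 its count is left out, as for the microenvironment.

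Called lists numbered 17 (tumor), 14 (microenvironment), 4 (difference of these), 24 (fractions in F4) and 23 (fractions in F0). With an estimated correlation there were 0 in each, and with fry 0, 0, 0, 16 and 7. The marker index gave 8 (tumor), 3 (microenvironment), 11 (fractions in F4) and 12 (fractions in F0), the omission of the 3 arrays gave 0 (tumor), and the processed values gave 8 (microenvironment). Leaving out an array gave 2 to 19, 2 to 18, 1 to 12, 21 to 26 and 14 to 25 lists. It gave 0 to 2 higher and 0 to 8 lower genes for tumor F4 against F0, 0 to 1 lower in the microenvironment, 31 to 1960 higher and 51 to 1310 lower for the fractions in F4, and 0 to 277 and 1 to 393 in F0.

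Signs reversed for these values, none of which had passed the test except Mlana, H2-K1, Cited1 and Zeb1 between the F4 fractions. For the difference of changes between fractions, Ctla4 was -0.0703 without background correction, -0.0367 with normexp, -0.73 with array weights and -0.0741 with the marker index, Adh7 was 0.31 and H2-K1 0.19 with median scaling, H2-K1 0.36 without the 3 arrays, and B2m -0.0477 and Cd274 -0.15 with array weights. For the fractions in F0, Pgam2 was -1.41 with median scaling, -0.11 with the processed table, -0.52 with the marker index and -0.36 without the 3 arrays, and with the marker index B2m was 0.00323, H2-K1 0.64 and Mlana -0.85. For the fractions in F4, the marker index gave 0.0529 for B2m, 0.31 for H2-K1, -0.49 for Mlana, -0.39 for Cited1 and 0.30 for Zeb1. In the tumor fraction, Mlana was 0.0769 with array weights, 0.25 with the marker index and 0.13 without the 3 arrays, and Cd274 -0.0552 with the marker index. In the microenvironment, Cd274 was -0.0921 with the marker index and -0.20 without the 3 arrays, which also gave -0.80 for Ctla4 and -0.15 for H2-K1. Leaving out an array gave, for the difference of changes, H2-K1 from -1.47 to 1.0, B2m from -0.17 to 0.30, Cd274 from -0.62 to 0.81, Ctla4 from -1.62 to 1.71 and Mlana from -0.54 to 1.10; in the tumor fraction, Cd274 from -0.53 to 0.90, H2-K1 from -0.0351 to 1.17 and Mlana from -0.28 to 0.13; in the microenvironment, B2m from -0.0107 to 0.47, Cd274 from -0.46 to 0.65, Cd28 from -0.0133 to 2.99, Ctla4 from -1.10 to 2.23, H2-K1 from -0.43 to 2.04 and Mlana from -1.22 to 0.42; and for the fractions in F0, Pgam2 from -0.36 to 0.68.

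Of the 35 splits of the 8 F4 arrays into groups of 4, 2 called as many genes as the real split, with 1939 in the real split and 2783 in the highest other. Most of these splits do not part all 4 pools, so the count over all splits neither excludes nor shows chance. The highest other split set tumor_F4 A and microenvironment_F4 A, B and C against the rest, which points to a structure of the samples. Among the 8 splits that part all 4 pools, the highest other called 0 genes. This cannot decide on chance either, since 8 splits are too few. The others also mix the fractions within a group, which adds the fraction difference to the spread. For the lists 6 of the 35 splits called as many, with 24 in the real and 25 in the highest other split. The other splits each called 4 to 25 lists, nearly all with 0 genes, so the number of called lists cannot decide on chance. The 17 and 14 lists called for F4 against F0 (tumor and microenvironment) lie within that range. Within either line, the lymphocyte and neutrophil lists lay higher on every microenvironment array than on every tumor array. The neutrophil list averaged 8.57 to 10.09 against 4.68 to 7.35, which argues against chance for these lists.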

Other observations

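The values below were chosen after the data were seen, and the differences between single arrays were not tested.

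The F0 tumor arrays, from 2 pools, differed in immune and interferon genes. The interferon gamma response list averaged 9.39 on tumor_F0 B2 and 7.24 on tumor_F0 B3, class II presentation 8.35 and 5.70, class I presentation 8.83 and 7.40, the inflammatory cytokine list 8.53 and 5.81, the macrophage list 8.26 and 6.65 and the fibroblast list 7.38 and 5.44. The F4 tumor arrays ran from 8.14 to 9.19 in the interferon gamma response and from 6.63 to 9.42 in class II presentation, so they lay between the F0 arrays in the first list. The melanocyte list (10.24 and 10.30) and the T cell list (5.41 and 4.43) differed less between the F0 arrays. Within F4, tumor_F4 D was low in macrophage (6.42) and fibroblast (5.53) genes, against 8.18 to 9.88 and 7.06 to 7.52 on the other 3 arrays.

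Among the microenvironment arrays, fibroblast and matrix genes averaged 10.07 on microenvironment_F4 C and 8.91 on B, against 6.67 to 8.07 on the other 4. The cell cycle list was lowest on microenvironment_F4 C, at 7.50, against 7.90 to 9.12 elsewhere in that fraction. Erythroid genes averaged 10.67 to 12.64 on the microenvironment arrays and 7.40 to 8.82 on the tumor arrays other than tumor_F4 A, which had 10.15. Hs3st1, 9.32-fold higher in F4 tumor cells without passing the test, lay at 7.34 on tumor_F4 A and at 8.87 to 9.67 on the other 3 F4 tumor arrays.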
